A study of Mus musculus with 8 samples.

How the data were processed

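The libraries were made from C57BL/6 mouse macrophages grown from bone marrow mononuclear cells in DMEM with 10% FBS and 20 ng/ml M-CSF, the growth factor that drives macrophage differentiation. Cells were kept with or without interferon beta (IFN-β) for 64 h, sorted by flow cytometry and extracted with TRIzol. The IFN-β dose is written in the labels as 100 uU/ml, a unit kept here as written. The labels give 3 groups: untreated cells (Control, 3 libraries) and 2 sorted groups of treated cells, named Treated1 (3 libraries) and Treated2 (2 libraries). The series describes the libraries of each group as biological replicates. Its title speaks of subsets with high and low arginase 1, but the labels do not say which group is which, so the groups keep their names and no group was named from the data.

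The authors deposited 4 tables, 1 each for Treated1 against Control, Treated2 against Control, Treated2 against Treated1 and all treated libraries against Control. Each table holds the authors' whole-number read counts per gene with Ensembl identifiers, gene names and positions, per the file headers. The tables also hold the authors' log2 fold changes and adjusted p-values, per the file headers. Per the submitters' processing notes, bcl2fastq, HISAT2 and DESeq2 were used with the build GRCm38. Their versions, the read counter, its strand setting and the sort gates are not given in the sources used here. A gene marked as changed in the authors' deposited tables had an absolute log2 fold change above 1 and an adjusted p under 0.05. The counts of a library were identical in every table that held it. Each table held 1 line that named no gene and stayed out of library sizes and tests. What it held is not reported here.

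The table of all treated libraries against Control holds 23669 genes and all 8 libraries, and its counts were used for every test. Total counts per library ran from 17098238 to 18363760, and 18164 to 18769 genes had at least 1 count. The 10 most abundant genes took 11.6% to 15.4% of the counts, and mitochondrially encoded genes took 1.02% to 1.80%. A count of 3, used here as the floor of detection, was worth 0.160 to 0.181 CPM, the count divided by the library size on the usual scale. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 6.50 to 27.6), so each was counted as a separate replicate.

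The tests ran in R 4.3.3. Counts were fitted with edgeR 4.0.16 by its quasi-likelihood test (glmQLFit and glmQLFTest) with TMM library scaling, in 1 fit of 3 groups over all 8 libraries, so that Treated2 with its 2 libraries shared the estimate of the spread. Genes passing filterByExpr were tested, 13378 in all. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with no minimum fold. Every adjusted p of a gene is from this test unless another tool is named. TMM factors ran from 0.928 to 1.03 and the common biological coefficient of variation was 0.0952. Fold changes carry a standard error (SE) from the fit, and levels are CPM with TMM library sizes, as mean ± SD. The contrast of all treated libraries weighed Treated1 and Treated2 equally. Where a group held 1 to 3 counts in all, the ratio is given with its 95% counting interval, and where it held 0 a lower bound against the floor of 3 counts over the group.

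Gene lists (20 for macrophage biology, 9 for other cell types and 2 for RNA quality and handling), the comparisons, the tests, the alternatives and the rule for naming genes were all chosen before the data were examined. The 31 lists name 637 different genes, of which 553 were tested. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the 31 lists within a comparison. Camera with a correlation estimated per list, and fry, were alternatives. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. Counts of called list members are given from the adjustment over all tested genes and, where it differed, adjusted over the list alone.

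The rule for naming genes took, per pairwise comparison, Arg1 and Nos2; the 5 largest rises and 5 largest falls among called genes with at least 5 CPM in the higher group, no overlap between libraries and no predicted-gene or pseudogene name; the 2 members with the smallest p from each of the 8 biology lists with the largest share of called members; and the most abundant member of each list for other cell types, RNA quality and handling. Some genes that the rule takes are not reported here. Other genes named below, mostly further members of the lists, were chosen after their values were seen.

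Biological process terms of the authors' annotation column were tested for enrichment among called genes by the hypergeometric test. The background was the 10709 tested genes with any such term, and the 1742 terms with 10 to 500 genes in it were tested, with Benjamini-Hochberg adjustment. This test was added after the data were seen. On simulated lists, 1 of 20 random lists gave any term and all 10 planted terms were found.

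Each step was tested on counts simulated from the real means and library sizes with 200 changed genes. Of changes of 0.5, 1 and 2 on the log2 scale, the fit recovered 45.3%, 72.3% and 93.8% for Treated1 against Control (13122 genes), 26.9%, 72.7% and 90.8% for Treated2 against Control (13159 genes) and 31.8%, 62.7% and 87.9% for Treated2 against Treated1 (13161 genes). For all treated against Control the shares were 49.3%, 74.2% and 95.3% (13137 genes). False calls made up 5.52%, 4.58%, 7.63% and 8.33% of the calls. In the simulated Treated2 against Treated1 comparison, camera found a list of 30 genes shifted by 0.5 and called 0 of 30 random lists. Genes were drawn independently there, so this does not test camera on lists whose genes move together. For the interferon-stimulated genes the correlation estimated from the real libraries was 0.85 in this comparison.

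The alternatives were DESeq2 size factors or upper-quartile factors in the same fit, no filter, a stricter filter (at least 1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, a fit of the compared groups only, the replicate number as a block, a minimum fold of 2, protein-coding genes only, and leaving out each library in turn. Fits without the second libraries of both treated groups, and without the first and the third libraries of Treated1, were added after the data were seen. A fit that leaves a group with 1 library assumes that this library varies like those of the other groups. Of the identifiers in the tables, 23614 of 23669 were found in GENCODE mouse release 21, and 22250 of them had the same position there. Positions are given as in the deposited tables. Since the strand setting of the counting is not given, counts of a gene that overlaps another, on either strand, could hold reads of both.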

Results

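RNA sequencing counts were examined for 8 libraries of sorted mouse bone marrow-derived macrophages, 3 from untreated cells (Control) and 5 from cells kept with IFN-β for 64 h and sorted into Treated1 (3 libraries) and Treated2 (2 libraries). Each library held 17098238 to 18363760 counts. The comparisons asked how each sorted treated group differed from untreated macrophages and how the treated groups differed from each other. In a principal component analysis of the 8 libraries, the first component (57.8% of the variance) parted the Control libraries (-48.3 to -42.1) from all treated libraries (12.5 to 37.7). The second component (17.3%) parted Treated2 (28.3 and 31.96) from Treated1 (-25.1 to -6.34). The second library of each treated group lay nearer to Control on the first component, at 12.5 in Treated1 and 16.2 in Treated2, than the other treated libraries, which lay between 33.3 and 37.7.

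Arg1, which encodes arginase 1, the enzyme that splits arginine into ornithine and urea, was nearly absent from Control and abundant in Treated2. The series title speaks of subsets with high and low arginase 1. An Arg1 difference between the treated groups may thus be what the sort, whose gates are not given, selected. The gene (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484, minus strand, GRCm38) was at 0.057, 0.058 and 0.49 CPM in the 3 Control libraries. The first and the second of these lay under the floor of 3 counts, so folds against Control rest mostly on the third. Arg1 was at 5.80, 1.22 and 9.20 CPM in the Treated1 libraries and at 762 and 127 CPM in the Treated2 libraries. Its log2 fold change was 11.02 ± 1.11 (SE) in Treated2 against Control (2075-fold, adjusted p = 0.00013) and 6.35 ± 0.75 in Treated2 against Treated1 (81.8-fold, adjusted p = 0.0038). In Treated1 against Control it was 4.66 ± 1.63, which did not pass the test (adjusted p = 0.055, edgeR quasi-likelihood), although all 3 Treated1 libraries lay above all 3 Control libraries. That difference passed without the second Treated1 library (5.13, adjusted p = 0.027), without the first (4.67, 0.0049) or the second Treated2 library (4.67, 0.0054), with DESeq2 (4.73, 0.00098), with no filter (4.66, 1.7e-06) and from the compared groups only (4.66, 0.0042). By contrast, limma-voom did not call Treated2 against Control (10.94, adjusted p = 0.057). The call against Treated1 was lost without the first and the third Treated1 libraries (8.50, adjusted p = 0.107). Leaving out 1 library, the log2 fold change against Control ran in Treated2 from 9.22 (without the first Treated2 library) to 12.75 (without the third Control library), and in Treated1 from 4.05 (without the third Treated1 library) to 6.39 (without the third Control library). Treated2 against Treated1 ran from 4.56 without the first to 7.13 without the second Treated2 library. The authors' deposited tables give log2 fold changes of 4.73, 11.10 and 6.36 for these comparisons. Nos2, the inducible nitric oxide synthase that uses the same substrate, had 2 counts in all Control libraries together. Its counts were 18.3-fold higher in Treated1 (95% counting interval 4.72 to 156) and 15.0-fold higher in Treated2 (3.62 to 133), and Treated2 was not called against Treated1 (log2 fold change -0.28 ± 0.52, adjusted p = 0.78).

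**Figure D1:**
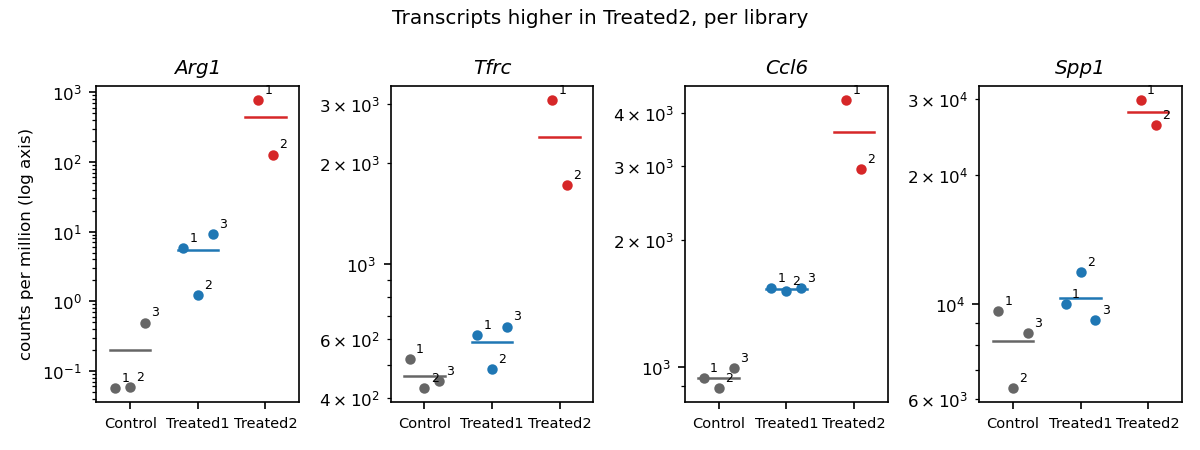
Levels of Arg1, Tfrc, Ccl6 and Spp1 in each of the 8 libraries, in CPM on log axes, with numbered points for single libraries by group and lines for group means. For Arg1, Control libraries lie at 0.057 to 0.49 CPM, Treated1 at 1.22 to 9.20 CPM and Treated2 at 127 and 762 CPM.

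Treated1 macrophages showed a broad interferon response with a fall in cholesterol synthesis genes. Ccl8 (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799, GRCm38), a chemokine that draws monocytes, went from 0.193 ± 0.243 CPM (SD, n = 3) in Control to 295 ± 85.4 CPM (n = 3), a 1508-fold rise (log2 fold change 10.56 ± 0.53, adjusted p = 3.3e-06) that ran from 9.97 without the third to 12.20 without the second Control library. Ly6a, the surface protein Sca-1, rose to 276 ± 114 CPM (9.56 ± 0.71, adjusted p = 2.1e-05). Slfn4, an interferon-induced Schlafen gene, rose from 1.24 to 304 CPM (7.93 ± 0.51). Itgax, which encodes the integrin CD11c, fell 7.09-fold, from 123 ± 21.7 to 17.4 ± 2.54 CPM (-2.83 ± 0.14, adjusted p = 3.3e-06). Scd1, the stearoyl-CoA desaturase of fatty acid synthesis, fell 14.8-fold, from 48.5 ± 5.19 to 3.28 ± 1.02 CPM (-3.89 ± 0.21, adjusted p = 4.4e-06).

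Of the 13378 genes tested, 3917 differed between Treated1 and Control, 2011 higher and 1906 lower, and 915 of them by at least 2-fold (652 higher, 263 lower). Genes that rose under the naming rule, which asks for at least 5 CPM in the higher group and no overlap between libraries, included Spon1 (1 count in Control, ratio 751, 95% counting interval 134 to 29717) and Apol9b (2 counts in Control, ratio 287, 79.2 to 2377). Those that fell under it included Sfrp5, a secreted Wnt antagonist (-3.04 ± 0.40), Mgll, the monoacylglycerol lipase (-2.67 ± 0.14), and Aldoc, a glycolytic aldolase (-2.53 ± 0.29). The authors' deposited table marks 843 genes (608 higher, 235 lower), and 823 of the 836 tested here were also called in the same direction. Without the third Treated1 library 2564 genes were called, and 2236 of the 3917 calls held in every fit that left out 1 library.

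All 45 type I interferon-stimulated genes rose in Treated1, with a median log2 fold change of 2.60 (camera adjusted p = 1.3e-93, adjusted p = 0.0805 with an estimated correlation). Oas3, an antiviral oligoadenylate synthetase, rose by 3.72 ± 0.21 and Ly6e by 2.92 ± 0.16 on the log2 scale. Of 16 guanylate-binding proteins and interferon-gamma-type chemokines, 14 rose (3.0e-21, adjusted p = 0.0805 with an estimated correlation), with Gbp6 up by 4.81 ± 0.22 and the GTPase gene Ifi47 by 2.24 ± 0.16. All 22 MHC class I presentation genes rose (8.6e-31, adjusted p = 0.0805 with an estimated correlation), among them the class I genes H2-Q7 (5.34 ± 0.28) and H2-Q4 (2.15 ± 0.10), close relatives whose reads the counting could split. Of 11 MHC class II presentation genes 9 rose (0.00022, adjusted p = 0.254 with an estimated correlation), including Ciita, the class II transactivator (1.22 ± 0.23), and Ctss, the cathepsin that trims the invariant chain (0.61 ± 0.09). Of 24 cell death and inflammasome genes 16 rose and 17 when adjusted over the list alone (2.3e-08, adjusted p = 0.0805 with an estimated correlation), among them the necroptosis kinase Ripk3 (1.55) and Casp4 (1.56).

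Of 15 monocyte chemokines and chemokine receptors 12 rose and 1 fell (9.8e-17, adjusted p = 0.0805 with an estimated correlation), with Ccr2, the receptor for Ccl2, up by 2.00 ± 0.09. Of 23 inflammatory cytokine and classical activation genes 11 rose and 3 fell (0.00016, adjusted p = 0.254 with an estimated correlation). Cxcl2 (3.09) and Acod1 (2.40) rose, and Marco (-3.11) and Saa3 (-1.85) fell. Of 24 immune regulation and checkpoint genes 13 rose, 14 adjusted over the list alone, and 5 fell (0.0013, adjusted p = 0.11 with an estimated correlation). Il1rn, the interleukin 1 receptor antagonist, rose by 1.84 ± 0.16 and Socs3, a brake on cytokine signalling, by 1.46 ± 0.15. Of 22 alternative activation genes 11 rose, 13 adjusted over the list alone, and 4 fell (0.047, adjusted p = 0.58 with an estimated correlation), and 7 rose by limma-voom, with the transglutaminase Tgm2 up by 0.85 ± 0.11 and the kinase Matk down (-1.004 ± 0.084). The call of this last list was lost without the first (adjusted p = 0.052) or the third Control library (0.13), and without the first (0.083) or the third Treated1 library (0.094).

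Cholesterol synthesis genes fell as a group in Treated1. Of 24 members 22 fell, 23 adjusted over the list alone, with a median log2 fold change of -1.01 (3.8e-27, adjusted p = 0.0805 with an estimated correlation). Dhcr7, a late reductase of the pathway, went from 51.5 to 26.1 CPM (-0.98 ± 0.06). Of 15 cholesterol efflux and LXR target genes 6 fell and 4 rose, 5 adjusted over the list alone (0.014, adjusted p = 0.16 with an estimated correlation). Of 38 cell cycle genes 16 rose, 22 adjusted over the list alone (4.3e-06, adjusted p = 0.52 with an estimated correlation). In the unfolded protein and amino acid stress list 8 of 26 rose and 1 fell, 9 and 1 adjusted over the list alone (0.014, adjusted p = 0.58 with an estimated correlation). Arginine and polyamine metabolism (7 of 23 up and 3 down, adjusted p = 0.060), oxidative phosphorylation (2 of 38 up and 8 down, 0.074), redox and NRF2 targets (7 of 27 up and 8 down, 0.18) and macrophage identity (6 of 21 up and 8 down, 0.12) did not pass the list test. Likewise, glycolysis (7 of 22 up and 6 down, 0.56), lysosome and phagocytosis (11 of 33 up and 9 down, 0.56) and hypoxia response (5 of 24 up and 5 down, 0.77) did not pass. Adjusted over the list alone the counts up and down were 8 and 3 for arginine, 7 and 9 for identity, 12 and 11 for lysosome and 6 and 5 for hypoxia. For glycolysis the median (0.064) and the mean (-0.065) differed in sign, as they did for lysosome (-0.042 and 0.17), and camera pointed up for both. Without the first Control library the unfolded protein list no longer passed (adjusted p = 0.052). Arginine metabolism passed without the first (0.032) or the third Control (0.032), the second Treated1 (0.038), the first (0.049) or the second Treated2 library (0.049). Oxidative phosphorylation passed without the first Treated1 library (0.025).

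Transcripts listed as markers of other myeloid cells were also higher in Treated1. Whether macrophages or other cells made them cannot be told from these values. Of 12 neutrophil markers 10 rose, 11 adjusted over the list alone (1.0e-06, adjusted p = 0.252 with an estimated correlation), and S100a9, a neutrophil calcium-binding protein, rose by 2.55 ± 0.64 (adjusted p = 0.014). Of 13 monocyte and progenitor markers 9 rose, 10 adjusted over the list alone (1.7e-12, adjusted p = 0.0805 with an estimated correlation), with Ly6c2 from 7.34 ± 3.12 to 540 ± 137 CPM (6.19 ± 0.34). Of 7 mast cell, basophil and eosinophil markers 6 rose and 1 fell (0.0020, adjusted p = 0.252 with an estimated correlation), with the eosinophil granule gene Prg2 up by 2.58 ± 0.27. Limma-voom called 3 of the 12 neutrophil markers, and DESeq2 10. Of the neutrophil markers, 11 were picked because the first and the third Treated1 libraries were their highest, a choice that favours these libraries. Over them the median log2 ratio to the Control mean was 2.40 and 2.58 in these libraries against 0.40 in the second. Without the first and the third libraries 865 genes were called, and S100a9 was at -0.076 and not called. In that fit all 3 lists kept their call, with means of 0.63 for neutrophil (from 2.30, adjusted p = 0.0061), 1.73 for monocyte and progenitor (from 2.39, 1.1e-14) and 1.76 for mast cell, basophil and eosinophil markers (from 2.33, 0.0021). The alternative activation (adjusted p = 0.30), unfolded protein (0.35) and stromal lists (0.067) lost theirs. The call of S100a9 was also lost without the first or the second Control library, or without the first or the third Treated1 library.

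Stromal and endothelial markers rose in 2 of 4 members (0.016, adjusted p = 0.252 with an estimated correlation), with Kdr, a receptor for the growth factor VEGF, up by 2.33 ± 0.18. T and NK cell (1 of 3 down, adjusted over the list alone 1 up and 1 down, 0.24), B cell (2 of 5 up and 2 down, 0.77), dendritic cell (1 of 4 up and 1 down, 2 and 1 adjusted over the list alone, 0.94), erythroid and megakaryocyte (1 of 3 up, 0.11) and osteoclast markers (3 of 7 up and 1 down, 0.77) did not pass as lists. Single members were Cd4 (-1.59 ± 0.18), Cd22 (-1.03 ± 0.16), Cd24a (-0.78 ± 0.16), the platelet factor gene Pf4 (1.26 ± 0.17) and Atp6v0d2, which was not called (-0.29 ± 0.14, adjusted p = 0.16). For the B cell list the median (0.82) and the camera direction (down) differed in sign, and for the osteoclast list the median (-0.12) and the mean (0.24). Of 16 sorting and handling stress genes 8 rose, and adjusted over the list alone 8 rose and 1 fell (0.00028, adjusted p = 0.0805 with an estimated correlation), with Jun up by 0.70 ± 0.09. Of 11 mitochondrially encoded transcripts 9 fell, 10 adjusted over the list alone (2.3e-09, adjusted p = 0.089 with an estimated correlation), with mt-Co1 down (-0.54 ± 0.08). Mitochondrial genes took 1.02% to 1.22% of the counts in Treated1, 1.19% and 1.39% in Treated2, and 1.64% to 1.80% in Control.

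**Figure D2:**
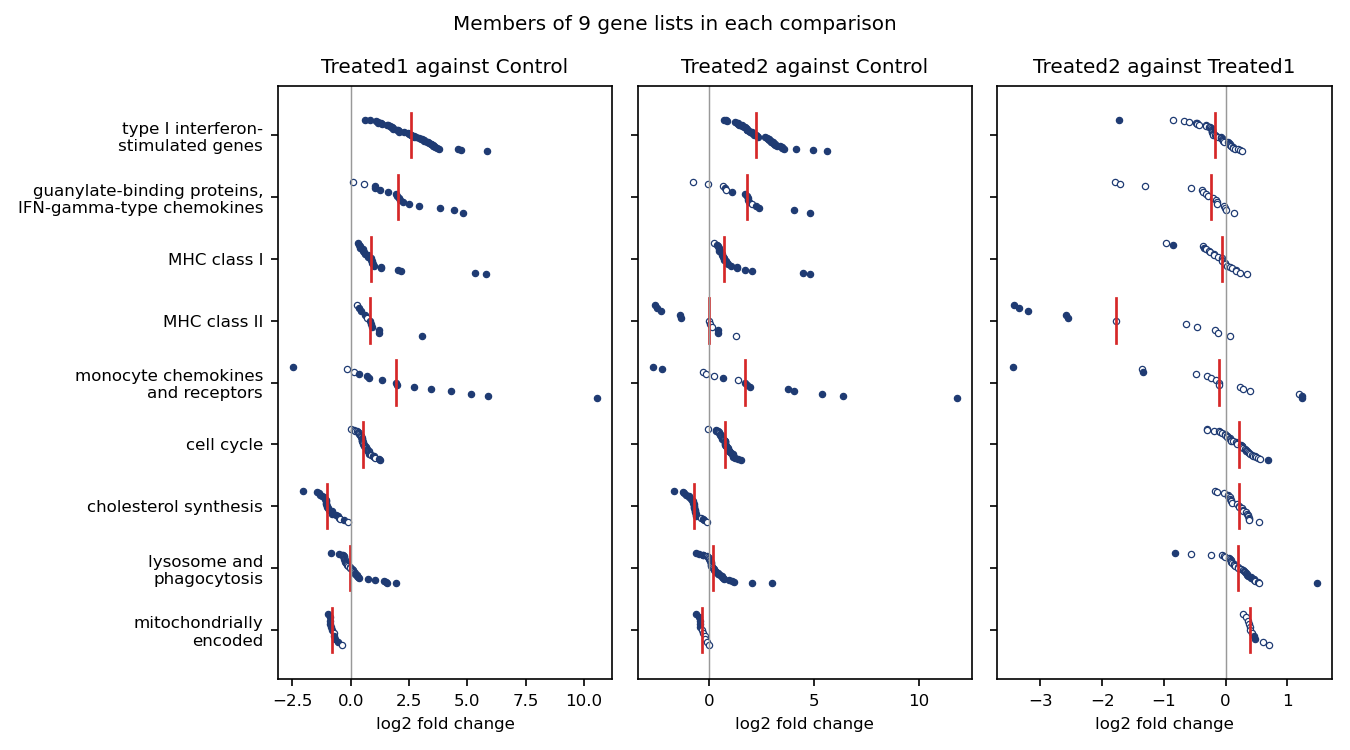
Log2 fold change of the members of 9 gene lists in 3 comparisons, with filled points for members called by edgeR, open points for the others and red lines for list medians. Interferon-stimulated genes lie far above 0 against Control in both treated groups (medians 2.60 and 2.25), and MHC class II presentation lies below 0 in Treated2 against Treated1 (median -1.77).

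Interferon-stimulated genes rose in Treated2 as well, Arg1 was far higher than in Control, and the MHC class II chain genes H2-Ab1 and H2-Eb1 were lower. Ccl8 rose 3565-fold (log2 fold change 11.80 ± 0.54, adjusted p = 3.9e-06), to 698 ± 304 CPM (SD, n = 2), and its log2 fold change ran from 11.21 without the third to 13.44 without the second Control library. Ly6a rose to 383 ± 250 CPM (10.03 ± 0.72, adjusted p = 2.6e-05). Retnla, which encodes the alternative activation product RELMα, had 0 counts in Control and 227 in Treated2 and was at least 120-fold higher (floor of 3 counts over the Control group). Nearly all of it came from the first Treated2 library, at 12.7 CPM against 0.944 CPM in the second. H2-Ab1 and H2-Eb1, whose products present peptides to helper T cells, fell from 42.3 ± 7.78 to 7.07 ± 0.655 CPM (-2.58 ± 0.28, adjusted p = 0.00020) and from 38.1 ± 8.85 to 6.81 ± 0.777 CPM (-2.48 ± 0.30).

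In all, 3939 genes differed between Treated2 and Control, 2051 higher and 1888 lower, 956 of them by at least 2-fold (633 higher, 323 lower). Spon1 rose as well (ratio 313, 95% counting interval 55.6 to 12430). Genes that fell under the naming rule included Hpgd, the enzyme that inactivates prostaglandins (-4.58 ± 0.37), Sfrp5 (-4.39 ± 0.56), Lyz1, a lysozyme gene with the close paralog Lyz2 (-3.55 ± 0.40), Itgax (-3.34 ± 0.18, 10.1-fold lower) and Tmem176a, which overlaps Tmem176b (-3.34 ± 0.51). The authors' deposited table marks 811 genes (543 higher, 268 lower), and 798 of the 809 tested here were also called in the same direction. Without the first Treated2 library 1656 genes were called, and 1485 of the 3939 calls held in every fit that left out 1 library.

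All 45 interferon-stimulated genes rose in Treated2 as well, with a median of 2.25 (8.4e-79, adjusted p = 0.19 with an estimated correlation), Oas3 by 3.50 ± 0.22 and Ly6e by 3.13 ± 0.17. Of 16 guanylate-binding proteins and interferon-gamma-type chemokines 11 rose (3.5e-14, adjusted p = 0.19 with an estimated correlation), with Gbp6 up by 4.81 ± 0.23 and Ifi47 by 2.22 ± 0.17. Of 22 MHC class I genes 21 rose (4.9e-24, adjusted p = 0.19 with an estimated correlation), with Nlrc5, the class I transactivator, up by 1.34 ± 0.08 and H2-Q4 by 2.04 ± 0.11. Of 11 MHC class II genes 5 fell and 2 rose, with a list median of -0.00074 and a mean of -0.70 (0.015, adjusted p = 0.39 with an estimated correlation). The 5 that fell were H2-Aa (-2.27), H2-Ab1, H2-Eb1, the invariant chain Cd74 (-1.37) and Ciita (-1.33), and the proteases Ctss (0.44) and Lgmn (0.42) rose. The list call was lost without the second Treated2 library, with little change in the mean (-0.74, adjusted p = 0.098), as was the call of Ciita, while both chains kept theirs without any single library.

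Of 38 cell cycle genes 28 rose in Treated2, 30 adjusted over the list alone (3.6e-09, adjusted p = 0.385 with an estimated correlation), with cyclin B1 (Ccnb1) up by 0.97 ± 0.13 and the replication helicase gene Mcm4 by 0.76 ± 0.12. Of 24 cholesterol synthesis genes 22 fell (7.6e-15, adjusted p = 0.205 with an estimated correlation), with Srebf2, the regulator of the pathway, at -0.73 ± 0.08. Of 15 cholesterol efflux and LXR targets 6 fell and 3 rose (0.014, adjusted p = 0.205 with an estimated correlation). Of 33 lysosome and phagocytosis genes 15 rose and 4 fell (0.0010, adjusted p = 0.385 with an estimated correlation), among them the protease Ctsl (3.02) and the lysosomal membrane protein Lamp2 (0.50). Of 15 monocyte chemokines and receptors 9 rose, 10 adjusted over the list alone, and 2 fell (5.1e-11, adjusted p = 0.19 with an estimated correlation). Of 22 alternative activation genes 10 rose, 11 adjusted over the list alone, and 3 fell (0.024, adjusted p = 0.47 with an estimated correlation). Ccl24 had 2 counts in Control and a ratio of 92.5 (95% counting interval 25.05 to 773) in Treated2, and the mannose receptor Mrc1 rose by 2.20. Of 23 inflammatory genes 8 rose, and adjusted over the list alone 9 rose and 1 fell (0.014, adjusted p = 0.39 with an estimated correlation). This list lost its call without the second Treated2 library (0.28), and alternative activation without the third Control library (0.068).

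Of 24 cell death genes 14 rose and 1 fell, 15 and 2 adjusted over the list alone (4.4e-06, adjusted p = 0.19 with an estimated correlation). In the unfolded protein list 7 of 26 rose and 1 fell, 9 and 1 adjusted over the list alone (0.022, adjusted p = 0.525 with an estimated correlation), with the chaperone Hspa5 up by 0.71. Of 38 oxidative phosphorylation genes 11 fell and 2 rose, 12 and 3 adjusted over the list alone (0.025, adjusted p = 0.47 with an estimated correlation). Immune regulation (10 of 24 up and 5 down, 0.066) did not pass, though Il1rn rose by 1.65 ± 0.17 and Entpd1, the ectonucleotidase CD39, fell (-1.64 ± 0.15). Arginine and polyamine metabolism (10 of 23 up and 2 down, 12 and 4 adjusted over the list alone, 0.073) and glycolysis (8 of 22 up and 3 down, 0.073) did not pass either, nor did hypoxia (6 of 24 up and 5 down, 6 and 6 adjusted over the list alone, 0.62), redox targets (6 of 27 up and 4 down, 0.47) and macrophage identity (3 of 21 up and 6 down, 3 and 7 adjusted over the list alone, 0.19). The hypoxia median (-0.017) and mean (0.060) differed in sign. The unfolded protein call was lost without the first Control (adjusted p = 0.077) or the first Treated2 library (0.16), and that of oxidative phosphorylation without the third Control (0.059) or the second Treated2 library (0.15). Arginine metabolism passed without the first Control (0.043) or the second Treated2 library (0.017), glycolysis without the latter (0.025), and immune regulation without the second library of any 1 group (0.025, 0.033 and 0.032).

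Of 12 neutrophil markers 3 rose and 1 fell in Treated2, 3 and 2 adjusted over the list alone (0.66, median -0.53 with camera pointing up), and S100a9 was not called (-0.42 ± 0.80, adjusted p = 0.73). Of 13 monocyte and progenitor markers 5 rose (0.00029, adjusted p = 0.205 with an estimated correlation), with Ly6c2 at 691 ± 248 CPM (6.55 ± 0.35). Of the 3 T and NK cell markers 1 fell, 2 adjusted over the list alone (0.0061, adjusted p = 0.19 with an estimated correlation), with Cd4, which macrophages also transcribe, from 18.5 to 2.15 CPM (-3.10 ± 0.24). B cell (2 of 5 down, 1 up and 2 down adjusted over the list alone, 0.066), dendritic cell (1 of 4 down, 0.17) and stromal and endothelial markers (1 of 4 up, 0.11) did not pass. Mast cell (1 of 7 up and 1 down, 0.90), erythroid (1 of 3 up, 0.098) and osteoclast markers (2 of 7 up and 2 down, 0.85) did not pass. The median, mean or camera direction differed in sign for the B cell, mast cell, erythroid and osteoclast lists. Their most abundant members were Cd22 (-0.77 ± 0.18), Cd24a (-1.26 ± 0.19), Kdr (1.60 ± 0.20), Prg2 (-0.36 ± 0.36, adjusted p = 0.49), Pf4 (2.27 ± 0.18) and Atp6v0d2 (0.25 ± 0.16, adjusted p = 0.27). Of 16 handling stress genes 7 rose and 2 fell (0.025, adjusted p = 0.24 with an estimated correlation), with Jun up by 0.50 ± 0.10. The calls of Cd22 and Jun were lost without the first Treated2 library. Of 11 mitochondrially encoded transcripts 5 fell, 6 adjusted over the list alone (0.016, adjusted p = 0.385 with an estimated correlation), and mt-Co1 was not called (-0.20 ± 0.09, adjusted p = 0.13). Without the first Treated2 library this list did not pass (0.062) and the erythroid list did (0.046). The B cell list passed without the third Control (0.013) or the first (0.014), the second (0.040) or the third Treated1 library (0.016), and the stromal list without the second Control library (0.035).

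Most genes called in both treated groups moved the same way against Control. Of them 1237 rose in both and 1083 fell in both, where independent lists of these sizes would share 308 and 269. Simulated unchanged groups against the same controls shared at most 1 and 0 in 20 runs. Since no gene was changed in these runs, they cannot show how many of the real shared calls come from the shared controls. Across genes, which are not independent replicates, the fold changes correlated at r = 0.77 (0.44 simulated), with a covariance of 0.438 against 0.0287 simulated, a difference of 0.409. Part of the excess overlap may come from the shared controls, since 3 Control libraries could not be divided into parts of at least 2. Without the first Treated2 library 1305 genes were called in both. With the treated groups averaged, 4512 genes differed from Control (2264 higher, 2248 lower, 891 by at least 2-fold), and 796 of the 822 tested genes marked in the authors' deposited table were also called in the same direction. A further 35 genes were called in opposite directions. Of these 19 were higher in Treated1 and lower in Treated2 than Control, among them H2-Aa, H2-Ab1, H2-Eb1, Cd74, Ciita and the fractalkine receptor Cx3cr1 (0.78 and -2.68). The other 16 went the reverse way, among them Layn (-0.59 and 0.99) and Cyp2j6 (-0.64 and 0.56), and all 35 also differed between Treated2 and Treated1.

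Treated2 differed from Treated1 in Arg1, which was 81.8-fold higher, and in the MHC class II chain genes H2-Ab1 and H2-Eb1, which were lower. The Arg1 difference may be what the sort selected, since the series title speaks of subsets with high and low arginase 1. Tfrc (chromosome 16, 32608920 to 32632794), the transferrin receptor for iron uptake, went from 585 ± 85.8 (SD, n = 3) to 2400.3 ± 962 CPM (n = 2; log2 fold change 2.04 ± 0.21, adjusted p = 0.0027). H2-Ab1 (chromosome 17, 34263209 to 34269418) was 10.7-fold lower (-3.42 ± 0.28, adjusted p = 0.0010) and H2-Eb1 10.2-fold lower (-3.35 ± 0.30, adjusted p = 0.0010). Cx3cr1 was 10.9-fold lower, 1.28 ± 0.192 against 14.1 ± 1.88 CPM (-3.45 ± 0.30, adjusted p = 0.0010), and Ccr2 fell from 60.1 ± 2.18 to 23.7 ± 4.19 CPM (-1.34 ± 0.10, adjusted p = 0.0010).

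In all, 1052 genes differed between the treated groups, 560 higher and 492 lower in Treated2, 206 of them by at least 2-fold (88 higher, 118 lower). The authors' deposited table marks 182 genes (84 higher, 98 lower), and 158 of the 181 tested here were also called in the same direction. The count depended on the fit, with 1661 genes when no filter was used and 486 from the compared groups only. It also changed without single libraries, to 178 without the first Treated1 library, 335 without the third and 1204 without the second. Without either Treated2 library it fell too, in fits that left this group with 1 library. It was 626 without the first Control library, which is not part of this comparison. Leaving out a library also leaves fewer to estimate the spread, so the falls cannot be laid to single libraries alone. Without the first and the third Treated1 libraries Tfrc (2.30, adjusted p = 0.053), Axl (-0.82, 0.093) and Prg2 (-2.41, 0.079) were not called. Of the 1052 calls 30 held in every fit that left out 1 library (17 higher, 13 lower), among them Arg1, Tfrc, H2-Ab1, H2-Eb1, Cx3cr1, Ccr2, the receptor kinase Axl (-0.81 ± 0.09) and Prg2 (-2.94 ± 0.33, adjusted p = 0.0035) from the named genes. Others of the 30, named after their values were seen, were H2-Aa (-3.20 ± 0.29), Cd74 (-2.59 ± 0.30), Ciita (-2.56 ± 0.31), the immunoglobulin gene Ighm (-2.22 ± 0.20), the integrin Itgal (-1.38 ± 0.13), Spp1, which encodes osteopontin (1.44 ± 0.17), the hypoxia-inducible factor gene Epas1 (1.61 ± 0.19) and the chemokine Ccl6 (1.24 ± 0.13).

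Of 11 MHC class II presentation genes 5 were lower in Treated2 than in Treated1, 7 adjusted over the list alone, with a median log2 fold change of -1.77 (3.7e-19, adjusted p = 0.28 with an estimated correlation, 0.031 by fry). The proteases of the list, Ctss (-0.17) and Lgmn (0.07), and H2-DMa (-0.12) were not called. The list kept its call without the first and the third Treated1 libraries (mean -1.36, adjusted p = 3.5e-24). Of 45 interferon-stimulated genes 1 was lower (0.16), of 22 MHC class I genes 2 were lower (0.25), and 0 of 16 guanylate-binding proteins were called by edgeR, DESeq2 or limma-voom, with 5 lower at an unadjusted p under 0.05. The last list passed by a narrow margin (camera adjusted p = 0.0499, adjusted p = 0.82 with an estimated correlation), and lost its call without the second (0.055) or the third Control library (0.055), the first (0.088) or the third Treated1 library (0.55), or the second Treated2 library (0.36). Without the second Treated1 or the first Treated2 library the interferon-stimulated list (means -0.36 and -0.46) and the MHC class I list (-0.23 and -0.27) passed as lower in Treated2. Without the first and the third Treated1 libraries the interferon-stimulated list passed as higher (0.28, adjusted p = 0.00011).

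**Figure D3:**
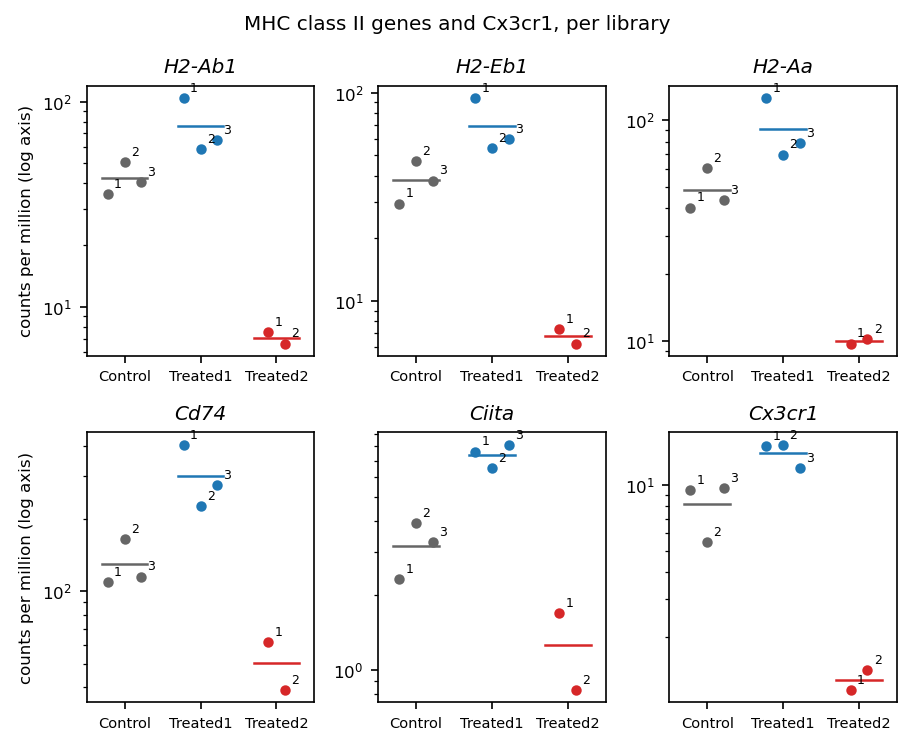
Levels of H2-Ab1, H2-Eb1, H2-Aa, Cd74, Ciita and Cx3cr1 in each library, in CPM on log axes, with numbered points for single libraries by group and lines for group means. H2-Ab1 averages 42.3 CPM in Control, 75.9 CPM in Treated1 and 7.07 CPM in Treated2.

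Other genes higher in Treated2 than in Treated1 under the naming rule included Retnla (5.67 ± 1.22, adjusted p = 0.034, 7 counts in Treated1), Cd5l, a macrophage scavenger protein gene (1.82 ± 0.41, adjusted p = 0.029), and the collagen gene Col18a1 (1.71 ± 0.34, adjusted p = 0.019). All lost their call without the first Treated2, the first Treated1 or the third Treated1 library, and Retnla also without the second Treated1 library. Those lower under it included Serpinb1a, a neutrophil protease inhibitor (-4.86 ± 1.09, adjusted p = 0.029), Elane, neutrophil elastase (-4.43 ± 0.80, adjusted p = 0.015), Rab44 (-4.42 ± 0.59, adjusted p = 0.0061), Camp, the cathelicidin of neutrophil granules (-4.42 ± 1.04, adjusted p = 0.034), and the adhesion molecule Vcam1 (-3.94 ± 0.90, adjusted p = 0.031). Rab44 lost its call without the first Treated2 library. The other 4 lost theirs without either Treated2 library or the first Treated1 library, and Serpinb1a, Camp and Vcam1 also without the third Treated1 or the first Control library. Camp was further lost without the third Control library. These transcripts were high in the first and the third Treated1 libraries, without which 14 genes were called, all lower in Treated2.

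Of 12 neutrophil markers 8 were lower in Treated2, 9 adjusted over the list alone (4.2e-09, adjusted p = 0.31 with an estimated correlation), with S100a9 at -2.97 ± 0.77 (adjusted p = 0.047), a call lost without any library other than the second Treated1 one. Limma-voom called 1 of the 12 as lower, and DESeq2 9. Of 13 monocyte and progenitor markers 4 were lower, 6 adjusted over the list alone, and 1 was higher (1.3e-05, adjusted p = 0.277 with an estimated correlation), while Ly6c2 was not called (0.36 ± 0.28, adjusted p = 0.47). Of 7 mast cell, basophil and eosinophil markers 2 were lower, 4 adjusted over the list alone (7.1e-06, adjusted p = 0.28 with an estimated correlation). Without the first and the third Treated1 libraries the mean log2 fold change of these lists was -0.81 (from -2.49), -0.47 (from -1.13) and -1.62 (from -2.02), and each still passed. Of 3 T and NK cell markers 2 were lower (0.0053, adjusted p = 0.28 with an estimated correlation, 0.0096 by fry), Cd4 (-1.51 ± 0.25, adjusted p = 0.013) and Nkg7, with 43 counts in Treated1 and 0 in Treated2 (at least 8.72-fold lower). B cell markers (1 of 5 lower, 2 adjusted over the list alone, 0.0093, adjusted p = 0.40 with an estimated correlation) and dendritic cell markers (1 of 4 lower, Dpp4 at -3.60, 0.042, adjusted p = 0.381 with an estimated correlation) also passed, while Cd22 (0.26 ± 0.18) and Cd24a (-0.48 ± 0.18) were not called. The B cell list lost its call without the first Treated2 library (adjusted p = 0.068), and the dendritic list without the third Treated1 library (0.13) or without the first and the third (mean -0.64 from -1.29, 0.18).

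**Figure D4:**
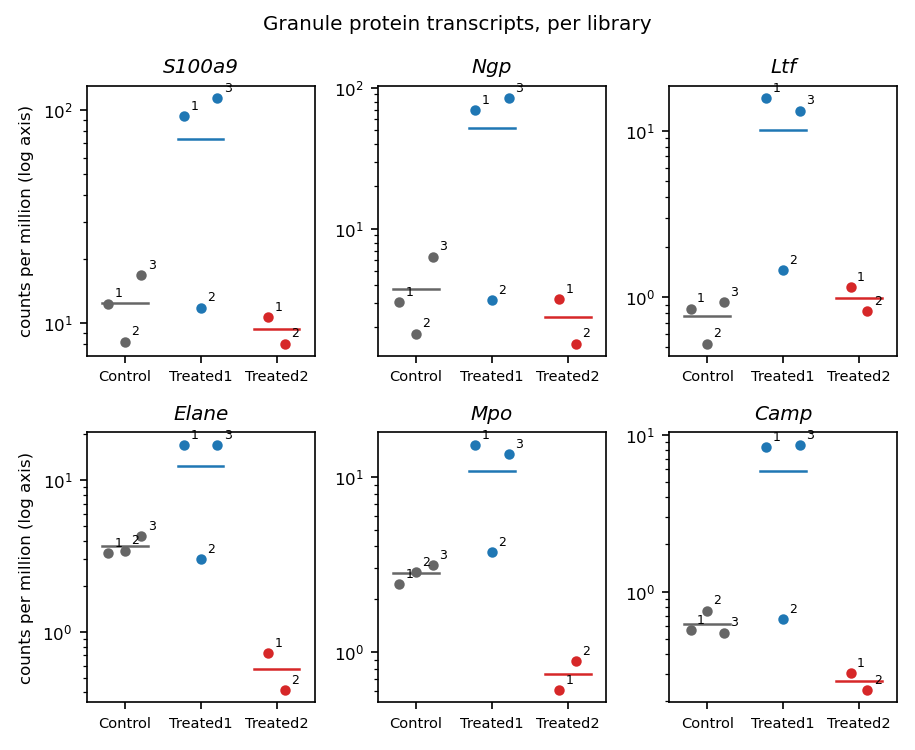
Levels of S100a9, Ngp, Ltf, Elane, Mpo and Camp in each library, in CPM on log axes, with numbered points for single libraries by group and lines for group means. The first and the third Treated1 libraries stand above the second. Over 11 neutrophil markers, picked because these libraries were their 2 highest, the median log2 ratios to Control are 2.40 and 2.58 against 0.40.

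Lysosome and phagocytosis genes were higher in Treated2 than in Treated1 in 10 of 33 members and lower in 1, 14 and 3 adjusted over the list alone (1.3e-05, adjusted p = 0.381 with an estimated correlation). Ctsl (1.48), Gusb (0.47), the clearance receptor Mertk (0.53 ± 0.07) and Lamp2 (0.37) were higher, and Axl, a related receptor, was the 1 lower member. Of 27 redox and NRF2 target genes 8 were higher and 1 lower, 9 and 1 adjusted over the list alone (0.0018, adjusted p = 0.42 with an estimated correlation), with sulfiredoxin (Srxn1, 0.44 ± 0.07) and thioredoxin (Txn1, 0.47 ± 0.09) higher. Cholesterol synthesis was higher as a list (median 0.22, 1 of 24 called and 0 adjusted over the list alone, 0.0056, adjusted p = 0.68 with an estimated correlation), as was cell cycle (median 0.22, 1 of 38 called, Ccnb1 at 0.69 ± 0.13, 0.019, adjusted p = 0.85 with an estimated correlation). Ccnb1 lost its call without the third Treated1 or either Treated2 library. The cell cycle call was lost without the second Treated1 (adjusted p = 0.15) or the second Treated2 library (0.13), and that of cholesterol synthesis without the latter (0.11). Of 11 mitochondrially encoded transcripts 2 were higher, 9 adjusted over the list alone (7.1e-06, adjusted p = 0.31 with an estimated correlation), and 8 by DESeq2, while mt-Co1 was not called (0.33 ± 0.09, adjusted p = 0.057).

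In the remaining lists few members differed between the treated groups and the list test did not pass. Alternative activation had 4 of 22 higher and 1 lower, 4 and 3 adjusted over the list alone (0.43), with the integrin Itgb3 (0.60 ± 0.11) and Ccl24 (2.93) beside Arg1 and Retnla, and Matk lower (-0.41 ± 0.10). Monocyte chemokines had 2 of 15 higher and 2 lower (0.21). Arginine and polyamine metabolism had 2 of 23 higher and 1 lower, 5 and 4 adjusted over the list alone (0.90), Arg1 and Oat (0.28) against Smox (-0.30). Hypoxia response had 2 of 24 higher and 2 lower, 5 and 2 adjusted over the list alone (0.77), with Hilpda, a lipid droplet protein gene, at 1.18 ± 0.18 and Ndrg1 at -0.60 ± 0.11. Cholesterol efflux and LXR targets had 1 of 15 higher and 2 lower, 1 and 4 adjusted over the list alone (0.77), with the oxysterol receptor gene Nr1h2 at -0.43 ± 0.07 and the lipid transfer protein gene Pltp at -0.75 ± 0.16. Macrophage identity had 3 of 21 higher and 2 lower, 4 and 5 adjusted over the list alone (0.92), with Aif1 at -0.88 ± 0.13. Among these named genes, Mertk, Srxn1, Txn1, Aif1, Nr1h2, Hilpda and Cd4 lost their call without the first Treated2 library, Itgb3 without it or the first Treated1 library, and Ndrg1 and Pltp without these or the third Treated1 library. Pltp also lost it without the second Treated2 library, and Matk without that, the first Treated2, the first or the third Treated1 or the first Control library. Without the second Treated2 library the alternative activation list passed (mean 1.12, adjusted p = 6.4e-07), as it did without the first and the third Treated1 libraries (1.56, 0.0045), and without the first Treated2 library the chemokine list passed as lower (-0.49, 0.033).

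Glycolysis (2 of 22 higher and 1 lower, 0.083), oxidative phosphorylation (2 of 38 higher and 1 lower, 2 and 2 adjusted over the list alone, 0.43), immune regulation (1 of 24 higher and 2 lower, 0.098) and cell death genes (3 of 24 lower, 0.50) did not pass. Nor did the stromal and endothelial (1 of 4 lower, Kdr at -0.73 ± 0.19, 0.27), erythroid (1 of 3 higher, Pf4 at 1.01 ± 0.17, 1 and 1 adjusted over the list alone, 0.77) and osteoclast markers (1 of 7 higher and 1 lower, 3 and 3 adjusted over the list alone, Atp6v0d2 at 0.54 ± 0.16, 0.92). Handling stress genes had 1 of 16 lower, 1 higher and 4 lower adjusted over the list alone (0.14), with Jun at -0.20 ± 0.10. The call of Pf4 was lost without either Treated2 library, and that of Kdr without either of them, the first or the third Treated1 library or the first Control library. In the inflammatory list 0 of 23 were called by edgeR, DESeq2 or limma-voom (0.20), with 3 lower at an unadjusted p under 0.05. In the unfolded protein list 0 of 26 were called by edgeR and limma-voom and 2 as higher and 1 as lower by DESeq2 (0.92), with 4 higher and 3 lower at an unadjusted p under 0.05. This list passed as lower without the first Treated2 library (mean -0.18, adjusted p = 0.023) and as higher without the second (0.18, 0.0065). Glycolysis (higher, 0.013) and the inflammatory list (lower, 0.0016) passed without the second Treated2 library, the latter also without the first and the third Treated1 libraries (-0.27, 0.025), and immune regulation (lower) without the second Treated1 (0.031) or the first Treated2 library (0.012). The median and mean differed in sign for arginine (-0.0043 and 0.28) and macrophage identity (0.066 and -0.018), and the camera direction differed from both for cholesterol efflux and erythroid markers.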

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

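All tests of explanations given here were chosen only after the result was seen, except those on the lists of immature granulocyte and dendritic cell transcripts, and the fits without the first and the third Treated1 libraries were added later. Results are listed here because the effects of the treated groups against the same Control libraries differed by a test of the difference itself. Between Treated2 and Treated1 this held for 1052 genes and 13 of the 31 gene lists by camera at its preset correlation. With an estimated correlation camera called 0 of the lists (4 at an unadjusted p under 0.05), and fry called 2. Of 50 genes named against Control, 20 differed between the treated groups, 13 of them lower and 7 higher in Treated2. The higher ones were Arg1 (log2 difference 6.35), Retnla (5.67), Ccl8 (1.24), Scd1 (1.13), Pf4 (1.01), Ccnb1 (0.69) and Dhcr7 (0.28). For Arg1 the difference may be what the sort selected. The lower ones were H2-Ab1 (-3.42), H2-Eb1 (-3.35), S100a9 (-2.97), Prg2 (-2.94), Ciita (-2.56), Hpgd (-2.39), Tmem176a (-2.05), Cd4 (-1.51), Ccr2 (-1.34), H2-Q7 (-0.86), Entpd1 (-0.75), Kdr (-0.73) and Matk (-0.41). Arg1, H2-Ab1, H2-Eb1, Ciita, Ccr2 and Prg2 held their call without any single library, and the other 14 lost it without the first Treated2 library. Cd4 lost it in that fit alone, and Tmem176a lost it whichever library was left out. The count of 1052 was 32 without the first Treated2 library, 511 without the second, 178 and 335 without the first and the third Treated1 library and 626 without the first Control library.

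The first pattern is lower MHC class II chain transcripts in Treated2 than in Treated1, with a median log2 fold change of -3.35 over H2-Aa, H2-Ab1 and H2-Eb1. Fewer dendritic cells in Treated2 could lower these chains, and 8 tested genes of 19 listed dendritic transcripts had a median of -0.0045 (95% bootstrap half-width 1.29), above -1.67, the bound fixed beforehand against that explanation. That bound was too lenient, because 5 of the 8 genes averaged 5 CPM or more in Treated2 (Mgl2 only through the first library, at 26.3 against 2.77 CPM), a baseline that hides a small share of cells, and this requirement was added after the values were seen. Of the list, 11 genes lay under the filter, with at most 11 counts, 6 stood in other lists, and Flt3, Zbtb46 and Cd209a had at most 6 counts. Over 5 B cell markers the median was -0.54 (half-width 1.24), so a dendritic or B cell share and a change within macrophages cannot be told apart here, and the sort, whose gates are not given, would remove such cells if it excluded them.

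The second pattern is granule protein transcripts in the first and the third Treated1 libraries. Immature granulocytes among the sorted cells are a candidate source. Of 20 listed transcripts, none in any other list used here, 14 were tested. In 78.6% of these (11 genes) both libraries were the highest of the 8, with no p given, since these genes are not independent. Itgb2l, Wfdc21, Trem3, Chil1 and Lrg1 stood at 0.44 CPM or less in every other library and passed the filter only through these 2. Their outcome was fixed by the filter, so a chance of 1 in 28 for a single gene does not apply. The count thus favours the first and the third Treated1 libraries. Of the 11, Lcn2 stood highest there, at 24.5 and 32.5 CPM against 1.56 CPM in the second Treated1 library. The other 3 of the 14, Padi4, Mcemp1 and Cebpd, were the only ones at 5 CPM or more in all Control libraries. Padi4 was highest in Treated2, at 18.3 and 17.7 CPM, and Mcemp1 and Cebpd were highest in the second and the third Control libraries. No listed transcript with such a level in Control thus followed the pattern. The strength of the interferon response cannot be told apart from this source. The first Treated2 library, with a like response (interferon-stimulated median 2.50, against 2.60 and 2.93), is a single library of another group. Its neutrophil median of -0.21 is over 11 markers picked because the first and the third Treated1 libraries were their 2 highest. Granule transcripts made by Treated1 macrophages themselves stay open and were not tested, and a sort on macrophage markers would remove granulocytes.

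The third pattern is a weaker response in the second library of each treated group, with interferon-stimulated medians of 1.98 in Treated1 and 1.95 in Treated2. Untreated-like cells mixed into these libraries would pull rising and falling genes back by 1 fraction, but falling genes kept more of their change than rising ones, by 0.269 in Treated1 (95% bootstrap interval 0.230 to 0.368) and 0.263 in Treated2 (0.195 to 0.348). These values rest on 22 falling and 107 rising genes in Treated1 and on 16 and 106 in Treated2. The bootstrap resampled genes of 1 library, which are not independent, so the intervals do not measure the spread between libraries. Depth was argued against, since the smaller total was 98.9% of the lowest among the other treated libraries. Shared preparation of libraries with the same number cannot be told apart from other sources. The deviations of the second Control library correlated at r = 0.16 with those of the second Treated1 library, above the bound set for this explanation. With the second Treated2 library r was 0.068, between the bounds set for either answer, and both values had to pass. Deviations of the Treated2 libraries mirror each other, so that value cannot speak for or against shared preparation. A biological difference between cultures was not tested and stays open.

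For Treated1 against Control, 1 of 10 splits of the 6 libraries, the real one, called as many genes. These splits are too few for a share under 0.05, with 3786 genes for the real split, in a fit of these libraries alone, and 0 for the highest other. For all treated against Control, 1 of 56 splits of the 8 libraries, the real one, gave as many, the smallest share these splits can give. Every other split mixed treated with Control libraries, which widens the spread within its parts. A chance split is thus unlikely but not excluded. In fits that knew only these 2 groups, the real split gave 3364 genes and the highest other 78.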

How the results depend on the processing

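The fits without the first and the third Treated1 libraries, and without the second libraries of both treated groups, were chosen only after the result was seen. Under DESeq2 size factors, upper-quartile factors and a stricter filter, all counts of calls lay within 1.5 times those reported and Arg1 kept its side of the threshold, and the counts over all genes of DESeq2, limma-voom and protein-coding genes lay within 1.5 times too, though not those of every gene list. No scaling moved the median of all genes by more than 0.1. Calls in Treated2 against Treated1 numbered 1661 with no filter and 486 from the compared groups only. A minimum fold of 2 left 915, 956, 206 and 891 genes, and 553 in both treated groups, by construction. Without the first and the third Treated1 libraries, where fewer libraries were compared, calls fell to 865 in Treated1, 14 in Treated2 against Treated1, 2808 in all treated and 783 in both. In that fit Arg1 was at 8.50 in Treated2 against Treated1 and no longer called, S100a9 in Treated1 turned to -0.076, and interferon-stimulated genes (0.28) and guanylate-binding proteins (0.073) turned upward in Treated2 against Treated1. Arg1 in Treated1 against Control became called with no filter (4.66), by DESeq2 (4.73), from the compared groups only (4.66) and without the second treated libraries (5.13), and in Treated2 against Control it was not called by limma-voom (10.94). By camera with an estimated correlation 0, 0 and 0 lists passed, and 10, 7 and 4 at an unadjusted p under 0.05. Fry called 21, 23 and 2 lists. The cause was not tested except where stated.

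Leaving out 1 library at a time, calls ranged from 2564 (without the third Treated1 library) to 4040 in Treated1, 1656 (without the first Treated2 library) to 4047 in Treated2, 32 to 1204 in Treated2 against Treated1 (32 without the first Treated2 library), 3254 to 4739 in all treated, and 1305 (without the first Treated2 library) to 2395 in both. Arg1 ranged from 4.05 to 6.39, 9.22 to 12.75 and 4.56 to 7.13, and lists called from 18 to 20, 17 to 20 and 10 to 17. The unfolded protein list in Treated2 against Treated1 ranged from -0.18 to 0.18. Over these fits of named genes 803 results kept their side of the threshold, 66 lost and 3 gained a call. The replicate block gave 4650, 4501, 1623, 5183 and 2891 calls and Arg1 at 4.69 (called) in Treated1. Under it 6 list calls were lost (MHC class II, inflammatory, oxidative phosphorylation and handling stress in Treated2, guanylate-binding proteins and dendritic markers in Treated2 against Treated1) and 7 gained (arginine metabolism in all 3 comparisons, immune regulation, B cell and erythroid markers in Treated2, alternative activation in Treated2 against Treated1). Of named genes 5 gained a call. The labels do not say that replicate numbers pair libraries, and same-number deviations correlated at 0.052, 0.16 and 0.15 between Control and Treated1, 0.061 and 0.068 between Control and Treated2, and 0.18 and 0.32 between Treated1 and Treated2, so no pairing was used. As a hint from the data, within Control and Treated1 each library correlated best with its own number. Library 3 of Treated1 has no counterpart of that number in Treated2. It correlated at 0.22 with library 1 and at -0.22 with library 2 of Treated2. Deviations within a group of 2 libraries mirror each other, so these values cannot speak for or against pairing. With 17098238 to 18363760 counts per library, levels under 0.160 to 0.181 CPM could not be told from 0.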

Other observations

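The enrichment of annotation terms was chosen only after the result was seen, as were the genes named here. Genes of DNA replication initiation rose beside the interferon response. Of 21 such genes 14 rose in Treated2 against Control, where chance gives 3.44 (hypergeometric adjusted p = 6.9e-05), with a median log2 fold change of 0.68. In Treated1 10 of them rose, with a median of 0.50. Of 33 genes of the cellular response to interferon-beta 29 rose in Treated1 (chance 5.20, adjusted p = 8.3e-17) and 27 in Treated2. Among 25 cholesterol biosynthesis genes 19 fell in Treated1 (chance 3.74, adjusted p = 8.1e-09) and 17 in Treated2 (adjusted p = 1.2e-06). In all, 97 terms were enriched among rising and 5 among falling genes in Treated1, and 73 and 3 in Treated2. Between Treated2 and Treated1 the hypergeometric test gave 0 terms in either direction, with 82 among higher and 87 among lower genes at an unadjusted p under 0.05. The enrichment was not repeated without single libraries.

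Most ribosomal protein genes that carry the term cytoplasmic translation, whose products build the ribosome, were lower in both treated groups. Ribosomal protein genes without that term were not examined. Of 30 protein-coding members 24 fell in each comparison with Control, with medians of -0.30 in Treated1 and -0.32 in Treated2, and 3 differed between Treated2 and Treated1. Reads shared with their pseudogenes were not measured. Of the 92 genes of the term cytoplasmic translation, which holds them, 41 fell in Treated1 and 47 in Treated2, and 0 rose. The term had medians of -0.29 and -0.36 under TMM, -0.29 and -0.36 under DESeq2 size factors and -0.30 and -0.39 under upper-quartile factors. Among genes whose difference between the treated groups held without any single library, Maoa, a monoamine oxidase, was higher in Treated2 (1.14 ± 0.13, SE), as were Serpinb6a, a protease inhibitor (1.09 ± 0.13), Glb1, the lysosomal galactosidase (0.63 ± 0.07), and Cyp2j6 (1.19). Plbd1, a phospholipase-like gene, was lower (-2.39 ± 0.25).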
